A study of Mus musculus with 12 samples.

How the data were processed

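Total RNA of whole ovaries, or of 0.25 of a testis, was labelled with biotin and measured on arrays, per the labels' protocols. Adult organs came from single animals perfused with saline, and 300 ng of RNA was labelled per array, per the labels' protocols. P3 ovaries were not perfused, more than 10 females were pooled per array, and 1 µg of RNA was labelled by a CodeLink protocol, per the labels' protocols, although MAS5 and the form of the probe set names belong to Affymetrix arrays. This conflict in the labels was not resolved. Adult and P3 arrays therefore differ in platform, labelling, pooling and normalization.

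The deposited adult values are on a log2 scale and were made by the authors with RMA in the Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalizes between arrays and summarises the probes of each probe set. Medians of the 8 adult arrays lay between 4.83 and 4.94. The deposited P3 values are MAS5 signals, a linear intensity, per the submitters' processing notes. On each of the 4 P3 arrays the mean after trimming 2% at each end was 500, so each array had been scaled to the same level. Software versions of the authors' steps are not given in the sources used here. The replicate samples of the adult set are separate animals, and the P3 samples are separate pools. No array repeated another (within groups r across genes was 0.969 to 0.996).

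The gene of each probe set was taken from the platform annotation supplied with the values. On the adult array 23410 of 35557 probe sets were listed with a gene, 1621 of them with several, leaving 21789 with a single gene, and 12147 were unnamed here. On the P3 array 35890 of 45101 were listed, 932 with several, leaving 34958, and 9211 were unnamed here. Symbols were updated by gene identifier through the RefSeq gene table of assembly GRCm38.p6, used for names only, and 91 adult and 204 P3 probe sets with a single gene kept their older symbol. For a gene with several probe sets, the one with the highest mean over all arrays of its platform was used. No coordinates are given, since no genome build is named for the arrays.

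Tests were made in R 4.3.3 with limma 3.58.1. The 8 adult arrays were fitted together with one mean per group, so that the 3 groups shared one estimate of the spread, and the 4 P3 arrays were fitted alone as log2(signal + 16). Fits used lmFit and eBayes with an intensity trend, tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the platform. A fold change at P3 is on the log2(signal + 16) scale and understates the change of dim genes. No test was made across the 2 tables. Every column of both tables was used.

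For gene groups, 21 lists were fixed from knowledge of gonadal cell types and pathways: Sertoli cell, granulosa cell, oocyte, steroidogenic, corpus luteum, spermatocyte and spermatid, spermatogonia, meiotic prophase, Wnt pathway, cell cycle, cholesterol synthesis, tight and gap junction, collagen and basement membrane, smooth muscle, leukocyte, endothelial, erythrocyte, adipocyte, oviduct, epididymis and Y-linked. A few genes stand on more than one list, such as Cldn11, Wnt4 and Rspo1. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Named genes were Foxl2 and Xist, members of the lists as examples, the 10 largest rises and falls per comparison among genes past the threshold whose groups did not overlap (leaving out predicted, olfactory, vomeronasal and antigen receptor genes), and the 10 genes with the largest smaller change of those shared by the adult and P3 comparisons. The tests, lists, naming rule and these alternatives were fixed before the processed files were opened. Counts of list members without each adult wild-type ovary or with the ovaries alone were added after the difference between those 2 ovaries was seen, and so were the test of gene families and the fits with a separate wild-type ovary for mutant ovary and testis.

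Of the lists the results do not describe, these missed the threshold. Against wild-type ovary, adult mutant ovaries gave medians of -0.35 for collagen (1 of 12 genes rose, 1 fell), 0.36 for erythrocyte (1 of 2 rose), -0.79 for adipocyte (0 of 7), -0.03 for oviduct (0 of 5) and -0.06 for epididymis (0 of 6). Collagen was called without mutant ovary 3 (-0.46) and adipocyte without wild-type ovary 1 (-1.41). In testis against wild-type ovary the medians were 0.02 for spermatogonia (3 of 10 rose), -1.46 for Wnt (2 rose, 7 fell), 0.26 for cell cycle (7 rose, 5 fell), -1.65 for cholesterol (1 rose, 7 fell), -0.18 for junctions (4 and 4), -1.79 for smooth muscle (1 and 6), -0.83 for adipocyte (0 and 3), -0.33 for oviduct (1 and 3), -0.08 for epididymis (1 and 0) and 0.59 for erythrocyte (1 and 0). Cholesterol and adipocyte were called without wild-type ovary 1 (-2.52 and -1.55). For mutant ovary against testis the medians were 2.16 for steroidogenic, -0.12 for spermatogonia, 1.16 for Wnt, 0.41 for cholesterol, 0.30 for smooth muscle, -0.23 for erythrocyte, 0.13 for adipocyte, 0.36 for oviduct and 0.00 for epididymis. At P3 they were 0.19 for steroidogenic (1 of 8 fell, Hsd3b1), -0.08 for corpus luteum, -0.17 for spermatids, -0.36 for spermatogonia, 0.12 for meiosis, 0.31 for Wnt, 0.14 for cholesterol, 0.15 for junctions, -0.14 for collagen, 0.01 for smooth muscle, 0.04 for leukocytes, -0.01 for erythrocyte, 0.40 for oviduct, 0.53 for epididymis and -0.27 for Y-linked genes, with no other member past the threshold. Wnt was called without P3 wild-type ovary 1 (0.48) and meiosis without P3 wild-type ovary 2 (0.43).

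Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 30% of genes (at P3 also 50%), averaging all probe sets of a gene, testing every probe set, fitting only the compared groups, no intensity trend, pseudocounts of 1 and 64 at P3, a 2-fold minimum, the replicate number as a block, and leaving out each array in turn.

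The scripts were tested on simulated data, after their first run on the real files and before the final one, drawn from the real means and residual spread, with 200 changed genes. In the adult comparison of mutant and wild-type ovaries (19938 genes), 91.0% of genes changed by 1 log2 unit and 100% of those changed by 2 or 3 were recovered, with 9 unchanged genes called. In the P3 comparison (18194 genes), 40.3% were recovered at 1 log2 unit, 80.6% at 2 and 100% at 3, with 14 unchanged genes called. A list raised by 1 was called in both (adjusted p = 2.69e-34 and 3.15e-18), and of the other lists 1 was called in the adult simulation, which shares Cldn11 with the raised list. The simulated noise was independent between genes and had the same spread in every group. The 2 adult wild-type ovaries varied more, with r = 0.976 across genes beside 0.989 to 0.996 within the other adult groups. These rates may therefore be too favourable for the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.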

Results

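Gene expression was measured with arrays in mouse gonads that carry or lack Foxl2, a forkhead transcription factor of the granulosa cells that surround the oocyte. The adult set held 8 arrays of single animals at 8 weeks: 2 wild-type ovaries, 3 ovaries in which a floxed Foxl2 gene was combined with a Cre transgene, and 3 wild-type testes. The labels give these mutants as Foxl2 flox/flox x CreEBD. The newborn set held 4 arrays at postnatal day 3 (P3), 2 of wild-type ovaries and 2 of Foxl2 knockout (KO) ovaries, each made from pooled RNA of more than 10 females. The adult table held 35557 probe sets and gave 19938 genes. The P3 table came from another array platform, held 45101 probe sets and gave 18194 genes. For arrays, the number of samples per group limits the precision. Fold changes are given on the log2 scale with the standard error (SE) of the fit.

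Foxl2 itself was lower in every mutant array. On the adult arrays its RMA level was 8.75 and 8.81 in the wild-type ovaries and 5.81, 6.04 and 5.73 in the mutant ovaries, beside 5.22 to 5.38 in the testes. The difference between mutant and wild-type ovaries was -2.92 ± 0.13 (SE, n = 3 and 2, limma adjusted p = 5.08e-07). At P3 its MAS5 signal was 814.5 and 829.9 in the wild-type pools and 186.4 and 153.7 in the KO pools, a change of -2.18 ± 0.21 on the log2(signal + 16) scale (n = 2 and 2, adjusted p = 0.0235). Averaged with a second Foxl2 probe set, whose signals were 12.3 or less, the P3 change of Foxl2 was -1.27 and did not pass (adjusted p = 0.23). Xist, the X-inactivation RNA of female cells, lay between 7.76 and 8.88 in all 5 adult ovaries and between 3.20 and 3.40 in the 3 testes. At P3 the Xist probe set with the highest mean gave 1819 to 4449 in the 4 pools.

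The comparison of adult mutant with wild-type ovaries asked which genes differ at 8 weeks in ovaries with the floxed Foxl2 gene and Cre. The labels used here do not state when the gene was deleted. Most measured genes of Sertoli cells, the supporting cells of the testis, rose, and a part of the granulosa cell genes fell. Sox9, the transcription factor that drives Sertoli cell fate, rose by 3.68 ± 0.14 (SE), and Dmrt1, a factor that maintains male fate in the testis, by 2.69 ± 0.15. Fst, which encodes the activin-binding protein follistatin, fell by 3.49 ± 0.16, and Nr5a2, a nuclear receptor needed for ovulation, fell by 3.74 ± 0.16. In all, 3232 of 19938 genes passed the threshold, 1905 of them higher and 1327 lower in the mutant ovaries (limma, Benjamini-Hochberg adjusted p under 0.05).

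Of 15 measured Sertoli cell genes, 11 rose and 0 fell, over all genes and also adjusted over the list alone. The median of the list was 2.47 (camera adjusted p = 6.78e-12), and its call was the only one of the 21 lists in this comparison that held with an estimated correlation (adjusted p = 0.0304). Besides Sox9 and Dmrt1, the risers included Sox8, a relative of Sox9 (2.81 ± 0.15), Gata1, a zinc finger factor (2.47 ± 0.17), Dhh, the hedgehog ligand of Sertoli cells (1.55 ± 0.21), and Cldn11, a tight junction protein (4.44 ± 0.17). The β-defensin genes Defb19 and Defb36 rose by 3.45 ± 0.23 and 3.94 ± 0.18. The list members Ptgds (0.64 ± 0.31), Fgf9 (0.12 ± 0.16), Col9a3 (-0.10 ± 0.13) and Vnn1 (-0.16 ± 0.28) did not pass, though Ptgds did without mutant ovary 2 (0.97). With the ovaries alone in the fit, 9 of the 15 genes rose.

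**Figure D1:**
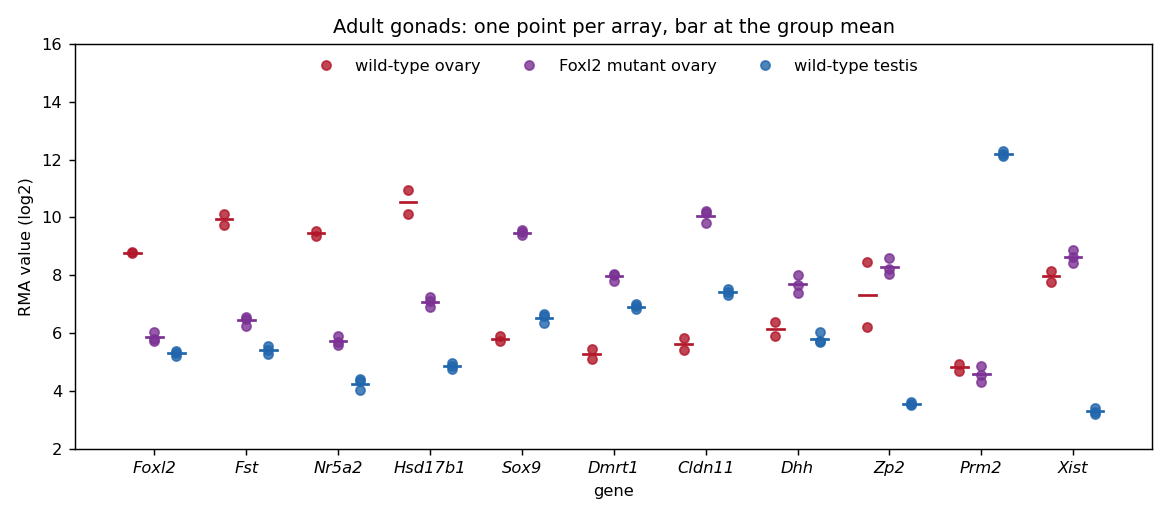
RMA values (log2, vertical axis) of 11 genes on the 8 adult arrays, with one point per array and a bar at the mean of 2 wild-type ovaries, 3 Foxl2 mutant ovaries and 3 wild-type testes. Sox9, Dmrt1, Cldn11 and Dhh lie higher in the mutant ovaries than in both other groups, and Prm2, a spermatid gene, is high in the testes alone.

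Granulosa cell genes moved apart. Of 15 measured members 7 fell and 2 rose, and adjusted over the list alone 8 fell and 2 rose. Besides Fst and Nr5a2, the estrogen-producing enzyme gene Hsd17b1 fell by 3.46 ± 0.22, the inhibin and activin subunit gene Inhba by 3.21 ± 0.28, the estrogen receptor gene Esr2 by 2.41 ± 0.44 and the hedgehog ligand gene Ihh by 1.75 ± 0.23. Without wild-type ovary 1 the fall of Esr2 was -1.42. Amhr2, the receptor of anti-Müllerian hormone, and Kitl, the ligand of the germ cell receptor Kit, rose by 1.92 ± 0.29 and 1.22 ± 0.15. Inha, Wnt4 and Rspo1 did not pass, at -0.43 ± 0.19, -0.47 ± 0.18 and -0.10 ± 0.19, though Wnt4 passed without wild-type ovary 1 (-0.74) and Inha without wild-type ovary 2 (-0.73). The list's median was -1.001 (camera adjusted p = 4.92e-05), and its call was lost with an estimated correlation (adjusted p = 0.339). The 2 wild-type ovaries differed in this list, 13 of the 15 genes being higher in wild-type ovary 1. Without wild-type ovary 1 the list held 4 risers and 8 fallers, and without wild-type ovary 2 it held 2 risers and 11 fallers, at a median of -1.77. Without mutant ovary 3 the median was -0.66.

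Of 9 measured tight and gap junction genes 6 rose, among them Cldn11, which is also on the Sertoli cell list, Cgn (3.31 ± 0.21), Ocln (2.95 ± 0.14) and Espn, an actin-bundling protein of Sertoli cell junctions (2.25 ± 0.22). Gja1, the main gap junction gene of granulosa cells, fell by 1.09 ± 0.12. The median was 0.97 (camera adjusted p = 2.03e-04, and with an estimated correlation adjusted p = 0.146).

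Cell cycle genes fell in 13 of 14 measured cases. Top2a, a topoisomerase of dividing cells, fell by 2.42 ± 0.15, the proliferation marker Mki67 by 2.00 ± 0.13, and the cyclin genes Ccna2 and Ccnb2 by 1.95 ± 0.13 and 2.03 ± 0.34. The median was -1.01 (camera adjusted p = 7.09e-12, and with an estimated correlation adjusted p = 0.127). In the fit of the ovaries alone 9 of the 14 fell, and of the 14 genes 13 were higher in wild-type ovary 1 than in wild-type ovary 2.

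Markers of other somatic cells also differed between mutant and wild-type ovaries. All 7 smooth muscle genes fell, among them Actg2 by 2.29 ± 0.20 and Cnn1 by 1.69 ± 0.27, with a median of -1.07 (camera adjusted p = 1.85e-05, and with an estimated correlation adjusted p = 0.339). Leaving the testes out of the fit left 4 of these 7 calls. Of 7 endothelial genes 4 fell, among them Cdh5, the cadherin of vessel walls, by 1.24 ± 0.19, with a median of -0.98 (camera adjusted p = 0.00268, and with an estimated correlation adjusted p = 0.469). Without wild-type ovary 2 the endothelial call ended, at a median of -0.75 (adjusted p = 0.0989). Of 11 leukocyte genes 3 rose and 0 fell, and 6 rose adjusted over the list alone. Cd74, the invariant chain of antigen presentation, rose by 1.53 ± 0.23 and the macrophage marker Adgre1 by 0.73 ± 0.15, while the list's median was 0.62 (camera adjusted p = 4.20e-04, and with an estimated correlation adjusted p = 0.469).

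Of the germ cell lists, 1 gene passed. None of 20 oocyte genes passed in the mutant ovaries, with a median of 0.37 (camera adjusted p = 0.0532), although the 2 wild-type ovaries differed by a median of 1.60 over this list, 19 of 20 genes being higher in wild-type ovary 1. Without wild-type ovary 1, 16 oocyte genes rose and the median was 1.25 (adjusted p = 6.5e-12), and without wild-type ovary 2, 4 fell and the median was -0.34 (adjusted p = 0.0142). Without mutant ovary 3 the list was also called, at 0.53. None of 20 spermatocyte and spermatid genes and none of 12 meiotic genes passed, with medians of -0.14 and 0.06. The 3 Y-linked genes were not past the threshold either (median -0.13). Of 10 spermatogonia genes 1 rose, Id4, an inhibitor of basic helix-loop-helix factors (0.98 ± 0.15).

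Steroid and lipid genes changed in part. Hsd17b3, the testosterone-producing enzyme gene of the testis, rose by 0.90 ± 0.19, whereas Hsd3b1 and Fdx1, of progesterone synthesis and electron transfer, fell by 1.41 ± 0.24 and 1.33 ± 0.27, and without wild-type ovary 2 the value of Fdx1 was -0.82. With Scarb1, 3 of 9 measured steroidogenic genes fell and 1 rose, and adjusted over the list alone 4 fell and 2 rose (median -0.19, camera adjusted p = 0.653). Scarb1 (-0.93) missed the threshold without wild-type ovary 2 (-0.42), mutant ovary 1 (-0.82) or mutant ovary 2 (-0.93), and stood at -1.45 without wild-type ovary 1. Of 5 corpus luteum genes 0 passed (median -0.70), and without wild-type ovary 1 the list was called, at -2.15 (adjusted p = 0.00312). Of 12 cholesterol synthesis genes 2 fell, Sc5d by 1.30 ± 0.19 and Insig1 by 1.11 ± 0.27, and 4 fell adjusted over the list alone. Insig1 missed the threshold without wild-type ovary 2 (-0.59), mutant ovary 1 (-1.07) or mutant ovary 2 (-0.99). The median was -1.10 (camera adjusted p = 0.00333, and with an estimated correlation adjusted p = 0.659). All 12 cholesterol genes were higher in wild-type ovary 2 than in wild-type ovary 1, and without wild-type ovary 2 the list's call ended, at a median of 0.02 (adjusted p = 0.916). Of 10 Wnt pathway genes, Apcdd1 and Dkk3 fell by 1.22 ± 0.13 and 1.05 ± 0.22 and 1 rose (median -0.04).

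Among the genes with the largest changes, Cst9, a cystatin-like gene of the early testis, rose by 5.36 ± 0.15 and the membrane protein gene Ttyh1 by 5.16 ± 0.14. Nxf3, Aard, Clec12b, Lcn2, Septin14, Vsig1, Cstdc1 and Tmem114 followed, with rises between 4.55 and 5.02. The largest falls were those of Slc18a2, a vesicular monoamine transporter (-4.14 ± 0.56), Slc38a3, a glutamine transporter (-3.93 ± 0.50), and Akr1c14, a hydroxysteroid dehydrogenase (-3.88 ± 0.16). Nap1l5, Ephx2, Nr5a2, Thbs4, Fst, Hsd17b1 and Vcan fell by values between -3.81 and -3.30. In wild-type ovaries 1 and 2 Slc18a2 stood at 9.88 and 7.23, and Aard at 7.04 and 4.47. The size of these 2 changes therefore depends on which wild-type ovary is used. With the testes left out of the fit, 1731 genes passed, 1154 higher and 577 lower, and 1728 of these were among the 3232. With a change of at least 2-fold required in addition, 1119 genes passed, 781 higher and 338 lower.

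The comparison of adult testis with wild-type ovary measured how the organs themselves differ. Spermatid genes set the testis apart: all 20 spermatocyte and spermatid genes were higher there, with a median of 6.77, and all 12 meiotic genes, with a median of 4.83. Smcp, a sperm mitochondrial capsule gene, was higher by 8.32 ± 0.15 (SE, n = 3 and 2), and Prm2, a protamine that packs sperm DNA, by 7.38 ± 0.17. In both wild-type ovaries the spermatid list averaged 4.07, under the array medians of 4.86 and 4.88. The size of these differences may thus be set in part by the low end of the scale. Of 15 granulosa cell genes 14 were lower in testis, with Hsd17b1 at -5.68 ± 0.22 and Inhba at -5.77 ± 0.28. In all 12028 genes passed, 4864 higher and 7164 lower in testis, and 6909 of these differed at least 2-fold.

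In testis, 9 of 15 Sertoli cell genes were higher than in wild-type ovary and 3 were lower. Defb36, Ptgds and Cldn11 were higher by 2.20 ± 0.18, 2.17 ± 0.31 and 1.80 ± 0.17, Dmrt1 by 1.65 ± 0.15 and Sox9 by 0.73 ± 0.14, while Vnn1 was lower at -3.47 ± 0.28. The list missed the threshold (median 0.81, camera adjusted p = 0.0701) and passed without wild-type ovary 1 (0.99, adjusted p = 0.0274). The Leydig cell genes Hsd3b6 and Hsd17b3 were higher by 4.54 ± 0.34 and 3.09 ± 0.19, and 6 of the 9 steroidogenic genes were lower, Cyp11a1 at -3.45 ± 0.17. All 5 corpus luteum genes, 12 collagen and basement membrane genes, 11 leukocyte genes and 7 endothelial genes were lower in testis, with Sfrp4 at -7.38 ± 0.67 and Col1a1 at -3.54 ± 0.23. Of 20 oocyte genes 15 were lower (median -1.21), Bmp15 at -4.39 ± 0.49 and Zp2, of the egg coat, at -3.77 ± 0.49. Without wild-type ovary 1, 10 oocyte genes were lower and 1 was higher (median -0.46), Oosp1, Nobox, Dppa3, Zar1 and H1f8 no longer passing, and without wild-type ovary 2, 18 were lower (median -2.06). The 3 Y-linked genes were higher, Eif2s3y by 3.96 ± 0.13. Camera called the lists for spermatids (adjusted p = 1.94e-17), meiosis (9.24e-09), granulosa cells (5.51e-05), collagen (5.51e-05), endothelium (9.53e-04), leukocytes (0.0025), oocytes (0.0251), corpus luteum (0.0251) and Y-linked genes (0.028). With an estimated correlation the spermatid list alone kept its call (adjusted p = 0.00424), and the other 8 came to adjusted p values of 0.199, 0.403, 0.199, 0.462, 0.509, 0.648, 0.509 and 0.273 for meiosis, granulosa cells, collagen, endothelium, leukocytes, oocytes, corpus luteum and Y-linked genes.

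The largest differences in favour of testis were those of Smcp, Fabp9, Gk2, Allc, Ube2d2b, Crisp2, Marchf11, Iqcf3, Odf1 and Adam5, between 7.52 and 8.32. Smcp, Crisp2 and Odf1 are on the spermatid list, whose low ovary values limit the reading of this order. In favour of ovary they were those of Sfrp4, Ephx2, Akr1c14, Igfbp5, Akr1c18, Inhba, Lrrn1, Hsd17b1, Vcan and Greb1, between -7.38 and -5.34. Lrrn1 differed between the 2 wild-type ovaries, at 7.35 and 11.21, and without wild-type ovary 2 its difference from testis was -3.76 in place of -5.69.

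Set against testis directly, the mutant ovaries were higher in most Sertoli cell genes and lower in every spermatid gene. Of 15 Sertoli cell genes 12 were higher in mutant ovary than in testis and 1 was lower, with a median of 1.80 (camera adjusted p = 0.00344, and with an estimated correlation adjusted p = 0.15). Sox9 was higher by 2.95 ± 0.12 (SE, n = 3 and 3), Cldn11 by 2.64 ± 0.15, Gata1 by 2.41 ± 0.15, Sox8 by 1.80 ± 0.13 and Dmrt1 by 1.04 ± 0.13, while Ptgds was lower at -1.53 ± 0.28. All 20 spermatid genes were lower in the mutant ovaries (median -6.77, camera adjusted p = 4.03e-17, and with an estimated correlation adjusted p = 0.00443), Prm2 at -7.62 ± 0.15. Mutant ovaries stayed above testis in 14 of 15 granulosa cell genes, with Inha higher by 2.90 ± 0.17 and Nr5a2 by 1.46 ± 0.14, and in 16 of 20 oocyte genes, with Zp2 higher by 4.72 ± 0.44. The steroidogenic genes split, Hsd3b6 and Hsd17b3 at -3.76 ± 0.30 and -2.19 ± 0.17 and Hsd3b1 and Cyp11a1 at 3.23 ± 0.21 and 2.98 ± 0.15. In all 12328 genes passed, 7486 higher and 4842 lower in mutant ovary, and 7181 of these differed at least 2-fold.

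The largest excesses of mutant ovary over testis were those of Sfrp4, Igfbp5, Akr1c18, Krt19, Xist, Gpx3, Bmp15, Cnn3, Mmp2 and Zp2, between 4.72 and 6.25. The largest deficits were those of Smcp, Fabp9, Allc, Gk2, Adam5, Crisp2, Ube2d2b, Marchf11, Odf1 and Prm2, between -8.36 and -7.62. The spermatid list averaged 3.90 to 3.95 in the mutant ovaries, so these sizes too may be set in part by the low end of the scale. Camera also called the granulosa (adjusted p = 7.46e-04), oocyte (0.00344), corpus luteum (0.0352), junction (0.0011), collagen (5.07e-04), leukocyte (5.07e-04) and endothelial (0.00344) lists higher. It called the meiotic (1.43e-08), cell cycle (6.09e-04) and Y-linked (0.0118) lists lower. With an estimated correlation none of these 10 calls held, at adjusted p values of 0.357, 0.618, 0.471, 0.15, 0.15, 0.357, 0.428, 0.15, 0.294 and 0.15 in that order.

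How far the mutant ovary had moved toward testis was measured by setting the 2 differences from wild-type ovary side by side. Of the genes higher in mutant ovary, 645 were also higher in testis, where 465 would be shared by independent lists, and of the genes lower in mutant ovary, 914 were also lower in testis, against 477. Cst9, Cldn11, Defb36, Sox9 and Dmrt1 were among the first, and Foxl2, Fst, Nr5a2, Hsd17b1, Ephx2 and Akr1c14 among the second. A further 727 genes rose in mutant ovary and were lower in testis (684 for independent lists), and 264 fell and were higher in testis (324). Top2a belonged to the last set, at -2.42 in mutant ovary and 0.82 in testis. The counts for independent lists treat every gene as equally able to pass, so part of any excess may come from that assumption. Both comparisons use the same 2 wild-type ovaries. In 100 simulated data sets with no effect at most 2 genes passed in the mutant comparison, so that the simulated overlap of at most 1 gene sets no scale for these counts. The sign agreed in 57.4% of all genes, against 70.5% in the simulation. Across genes, which are not independent replicates, the 2 differences had r = 0.16, with a covariance of 0.135 against 0.0179 in the simulation (mean r = 0.599), a difference of 0.118. The simulation held no effects, so its sign agreement and its r come from the shared controls alone and set no scale for the data. It also gave every group the same spread. The 2 wild-type ovaries varied more, with r = 0.976 across genes beside 0.989 to 0.996 within the other adult groups. It may therefore understate the part of the shared controls, and 0.118 does not measure the excess. With mutant ovaries set against wild-type ovary 1 and testes against wild-type ovary 2, a choice made after the data were seen, 581 genes were higher in both (418 for independent lists) and 828 lower in both (474). With the wild-type ovaries exchanged, 636 were higher in both (507) and 940 lower in both (543), while 948 were higher in mutant ovary and lower in testis (732). The sign then agreed in 52.1% of genes either way, r was 0.10 and 0.08, and the covariance was 0.094 and 0.081. With 1 wild-type ovary per comparison the spread came from the other groups, and part of the excess with all arrays may come from the shared controls.

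**Figure D2:**
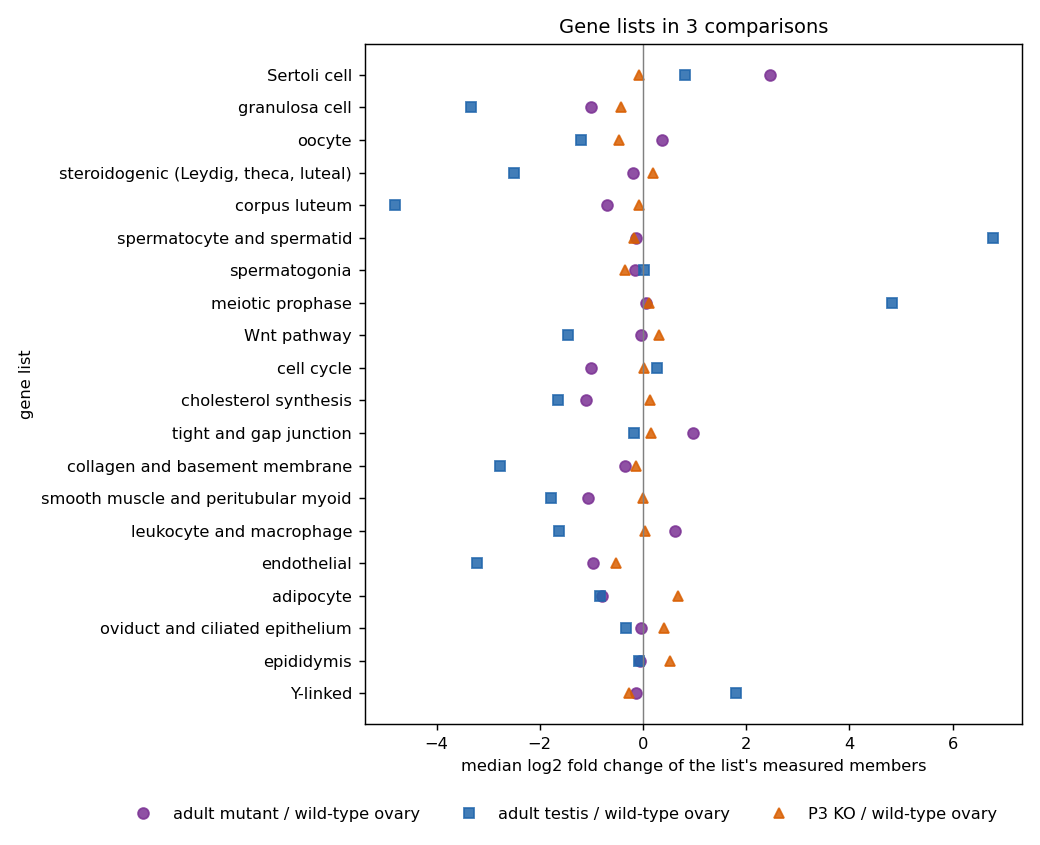
Median log2 fold change of the measured members of 20 gene lists (horizontal axis), against wild-type ovary of the same age, for adult mutant ovaries (circles), adult testes (squares) and P3 KO ovaries (triangles). The Sertoli cell list has its highest median in the adult mutant ovaries (2.47) and is near 0 at P3 (-0.08), and the spermatid list is high in testis alone (6.77). Some Sertoli cell list members were already bright in P3 wild-type ovaries, which limits the reading of the P3 median.

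The comparison of P3 KO with wild-type ovaries asked what the loss of Foxl2 does as follicles first form. Few genes passed, and on the log2(signal + 16) scale the steroid enzyme gene Hsd3b1 changed the most. Its signal was 1501.6 ± 252 (SD, n = 2) in the wild-type and 32.05 ± 1.48 in the KO pools, a change of -4.97 ± 0.25 (SE). Hsd17b1 fell by 3.09 ± 0.28 and Nr5a2 by 2.24 ± 0.26, as granulosa cell genes did in the adult. Nr0b1, which encodes the nuclear receptor DAX1, rose by 2.23 ± 0.14. In all 59 of 18194 genes passed, 25 higher and 34 lower in the KO ovaries (limma on log2(signal + 16), Benjamini-Hochberg), and 1733 had an unadjusted p under 0.05.

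Granulosa cell genes fell in 2 of 15 cases, Hsd17b1 and Nr5a2. Adjusted over the list alone 5 fell and 2 rose, with Fst at -1.40 ± 0.19, Inha at -0.99 ± 0.13 and Amh at -2.08 ± 0.52 beside Rspo1, a Wnt agonist of the ovary, at 1.31 ± 0.20 and Amhr2 at 0.48 ± 0.12. Rspo1 passed over all genes without P3 wild-type ovary 1 (1.60). The median was -0.43 (camera adjusted p = 0.00374, and with an estimated correlation adjusted p = 0.579), and without KO ovary 1 it was -0.25. Of 15 Sertoli cell genes 0 passed over all genes, at a median of -0.08 (camera adjusted p = 0.263), and 4 rose adjusted over the list alone. These were Dmrt1 (2.86 ± 0.53), Gata1 (2.12 ± 0.28), Cldn11 (1.11 ± 0.23) and Dhh (1.04 ± 0.15), while Sox9 stood at 0.86 ± 0.47 and its 3 probe sets disagreed in direction. The mean of the Sertoli cell list was 0.42. Some of its members were already bright in P3 wild-type ovaries, with mean signals of 4546 for Aard, 3237 for Defb19 and 3158 for Vnn1. Sox8 (46.95) and Cyp26b1 (29.9) lay under the wild-type array medians of 126.8 and 118.4. At P3 the list thus does not mark Sertoli cells alone, and its median cannot show that Sertoli cell genes stayed unchanged. Cell cycle genes had a median of 0.03 and none of 14 passed.

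Some oocyte genes fell in the KO pools. Oosp1, an oocyte-secreted protein gene, fell by 3.04 ± 0.20 and Zp1, of the egg coat, by 1.19 ± 0.13, the 2 of 19 measured that passed over all genes, and 10 fell adjusted over the list alone. Among these were Zar1 (-1.07 ± 0.20), Zp3 (-0.995 ± 0.168), Gdf9 (-0.94 ± 0.14) and the oocyte linker histone gene H1f8 (-0.94 ± 0.18). The transcription factor genes Figla, Nobox, Sohlh1 and Lhx8 did not pass on either count, at -0.11 ± 0.13, -0.16 ± 0.14, -0.19 ± 0.19 and -0.22 ± 0.12, nor did Dppa3 (-0.12 ± 0.12) and Nlrp5 (0.04 ± 0.14). The median was -0.47 (camera adjusted p = 2.56e-08, and with an estimated correlation adjusted p = 0.579). Of the endothelial and adipocyte lists, camera called the first lower (median -0.52, adjusted p = 0.0251) and the second higher (median 0.68, adjusted p = 0.0166), with no member past the threshold over all genes. Both were lost with an estimated correlation (adjusted p = 0.579 each). Without P3 wild-type ovary 1 both calls ended, at medians of -0.20 and 0.37, and without KO ovary 2 the endothelial call ended at -0.34. The adipocyte median was 1.34 without P3 wild-type ovary 2 and 1.04 without KO ovary 2.

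The 10 largest rises at P3 were those of Slc8a3, a sodium-calcium exchanger (4.42 ± 0.31), Scn3b, Bhmt, Nr0b1, Spon1, Acsbg1, Cst9, Smoc1, Cela3b and Tnni3, the last at 1.76 ± 0.13. The 10 largest falls were those of Hsd3b1, Apoa1, Slc26a7, Pramel29, Tfap2e, Hsd17b1, Oosp1, Fbxw13, Pla2g4c and Colec11, the last at -2.56 ± 0.17. Without KO ovary 1 or without KO ovary 2 the count of genes fell from 59 to 0, without wild-type ovary 1 to 21 and without wild-type ovary 2 to 5. It was 22 with all probe sets of a gene averaged, 213 without the dimmest 30% of genes, and 0 without the intensity trend of the variance (1737 at an unadjusted p under 0.05).

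Of 16553 genes measured at both ages, 25 passed in the same direction in adult mutant and P3 KO ovaries. Of these 13 were higher, where independent lists would share 2.77, and 12 were lower, against 2.40 (two-sided Fisher's exact p = 5.13e-07 and 1.65e-06). The Fisher test treats genes as independent, so these p values do not measure variation between animals or pools. Hsd17b1, Slc18a2, Apoa1, Ptges, Nr5a2, Foxl2, Ephx2 and Cnmd fell and Nr0b1 and Cst9 rose, each by more than 2 log2 units at both ages. Without adult wild-type ovary 1 the adult falls of Apoa1 (-2.45) and Cnmd (-3.04) were smaller, at -1.12 and -1.71, and without adult wild-type ovary 2 that of Apoa1 was -3.79. Ptges, a prostaglandin E synthase, fell by 2.40 ± 0.13 in the adult and by 2.52 ± 0.21 at P3, and Ephx2, an epoxide hydrolase, by 3.76 ± 0.40 and 2.14 ± 0.15. Smoc1, a matrix protein gene, passed in opposite directions. Across all genes the changes at the 2 ages had r = 0.14, and across the 57 genes called at P3 and measured at both ages r = 0.50. Of these 57 genes 61.4% changed in the same direction in the adult. Their P3 changes had r = 0.57 with the difference of adult testis from wild-type ovary, so r = 0.50 is not particular to the adult mutants. The tables were normalized separately on different platforms, so that a difference between ages was not tested, and the 25 shared calls fell to 0 without either KO pool, to 6 without P3 wild-type ovary 1 and to 1 without P3 wild-type ovary 2. They came to 10 with all probe sets averaged and to 78 without the dimmest genes.

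**Figure D3:**
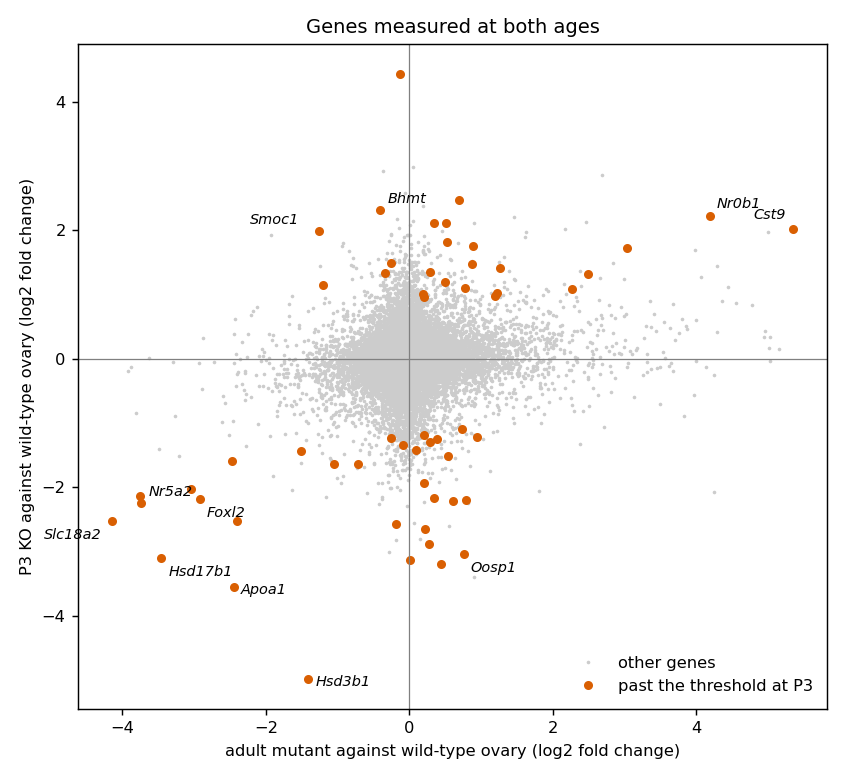
Log2 fold change of adult mutant against wild-type ovary (horizontal axis) and of P3 KO against wild-type ovary (vertical axis), one point per gene measured at both ages, with the genes past the threshold at P3 in colour. Foxl2, Nr5a2, Hsd17b1 and Slc18a2 lie low on both axes, Nr0b1 and Cst9 high on both, and Smoc1 changes sign.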

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

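All tests of explanations in this part were chosen after the result they bear on was seen.

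Among the genes named by rule or called at both ages, Smoc1 and Oosp1 had groups that did not overlap at either age, in opposite directions. Over all genes this was not rare: of the adult calls measured at both ages, 265 of 1831 higher and 200 of 1241 lower genes had P3 groups that did not overlap in the opposite direction, beside 560 and 383 in the same direction, where chance gives 16.7% each way. Smoc1 changed by -1.26 in the adult mutant ovaries and by 1.98 in the P3 KO ovaries, past the threshold both times. Oosp1 stood at 0.76 in the adult, which did not pass, and changed by -3.04 at P3, which did. The adult size depends on the wild-type ovary used. In testis against the same ovaries, Oosp1 moved from -0.88 to -0.40 without wild-type ovary 1 and to -1.35 without wild-type ovary 2. The difference between ages was not tested, since the 2 tables come from different platforms.

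Of 15 Sertoli cell genes 11 were higher in adult mutant ovaries than in wild-type ovaries and 12 than in testis. Testis tissue or RNA in the mutant samples is argued against by the most abundant testis transcripts: the spermatid list had a median of -0.138 against wild-type ovary, with Prm2 at 4.58 in mutant ovary, 4.82 in wild-type ovary and 12.2 in testis. A single aberrant array is argued against as well, since the list's median stayed at 2.19 or more with any of the 5 ovary arrays left out. The excess over testis may come from the RNA of germ cells, which make up much of the testis and dilute its somatic RNA: 100% of 30 collagen, endothelial and leukocyte genes were lower in testis than in wild-type ovary. A true difference in vessels, stroma and leukocytes between the organs was not separated from such dilution. The loss of Foxl2 itself, which the groups differ in by design, stays open as the biological explanation of the rise. An effect of the CreEBD transgene in the mutants was not separated from that loss.

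In the P3 KO pools 2 of 19 oocyte genes fell over all genes and 10 over the list alone, and the list's call was lost with an estimated correlation (adjusted p = 0.579). Fewer oocytes as the whole cause would lower all oocyte genes alike, yet their squared deviations from the common change were 15.6 times the squared standard error, from Oosp1 (-3.04) to Nlrp5 (0.04). The 10 genes that fell over the list alone had a median wild-type signal at the 96.8 percentile of all genes. Picking genes lower in KO favours a high wild-type signal, so this value alone cannot count against noise of dim probe sets. In the KO pools Zp3, Gdf9, Zar1, Zp1, H1f8 and Oosp1 had mean signals of 5951, 4887, 2424, 1288, 585 and 155. These lay above the KO array medians of 116.6 and 119.7, which argues against such noise for these genes. A change of transcription within oocytes, in response to KO granulosa cells, and a shift in follicle stage stay open and were not tested.

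Of 14 cell cycle genes 13 were lower in adult mutant ovaries, and the list's call was lost with an estimated correlation (adjusted p = 0.127). A lower share of granulosa cells was not excluded: of 15 granulosa cell genes 7 fell, while 2, Amhr2 and Kitl, rose. These 2 rises were known when the test was chosen, so they cannot decide the question. One wild-type ovary with unusually high cell cycle genes is argued against, because the median nearest to 0 with one wild-type ovary left out was -0.778. Follicles at different stages cannot be told apart from the genotype: oocyte genes differed by a median of 1.60 between the 2 wild-type ovaries themselves, and 2 such ovaries are too few to set that spread against the mutants. Granulosa cells that turned into slowly dividing Sertoli-like cells would be a biological explanation, which was not tested.

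For adult mutant ovary against testis, the 6 arrays make 10 splits of 3 and 3, too few for a share under 0.05. With only these groups in the fit the real split gave 12807 genes and was the 1 split with so many, and the highest of the others gave 0.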

How the results depend on the processing

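The settings in this part were planned before the files were opened, except the separate wild-type ovaries for mutant ovary and testis, chosen after the result was seen.

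Between adult mutant and wild-type ovaries the count of 3232 genes became 1731 with only the compared groups in the fit, which have fewer samples and a larger spread, and 1119 with a 2-fold minimum. Leaving out one array gave 2540 to 3760. The 2-fold minimum left 6909 genes for testis against wild-type ovary (10962 to 11441 with one array left out) and 7181 for mutant ovary against testis (11369 to 11862). At P3 the 59 genes became 90 with a pseudocount of 1, 213 and 190 without the dimmest 30% and 50% of genes, 22 with averaged probe sets, 27 with every probe set tested, 0 without the intensity trend (1737 at an unadjusted p under 0.05) and 0 to 21 with one array left out. The causes were not tested. The share of higher genes at P3 was 42.4%, and 50.2% and 53.2% without the dimmest genes.

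With the replicate number as a block, 2674 genes passed for adult mutant against wild-type ovary, 11433 for testis against wild-type ovary, 12136 for mutant ovary against testis and 300 at P3. Whether equal numbers pair the samples was not settled. The deviations of same-numbered arrays from their group means correlated below 0.1 (mutant and testis 0.079, 0.060 and 0.058, P3 0.040), but values this small cannot exclude a shared batch. In mutant ovary and testis each sample did correlate best with its own number, a hint from the data and not from the design.

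The r between the mutant and testis differences was 0.206 without wild-type ovary 1 and 0.182 without wild-type ovary 2 (0.144 to 0.206 over all left-out arrays). With a separate wild-type ovary for mutant ovary and testis it was 0.103 and 0.0832, with 1409 and 1576 genes in the same direction against 1559. Genes shared by adult mutant and P3 KO ovaries numbered 78 without the dimmest 30%, 10 with averaged probe sets and 0 to 28 with one array left out. With an estimated correlation camera called 1 list in each adult comparison and 0 at P3. Fry, which tests whether a list's genes move one way on balance, called 17 for testis against wild-type ovary and 16 for mutant ovary against testis. For adult mutant against wild-type ovary fry called 7, and 5 of these were called in the main test. Cholesterol (fry adjusted p = 0.221), leukocyte and endothelial (0.0539 each) were lost, and spermatids (0.012) and Y-linked genes (0.00504) were called lower. At P3 fry called 5, of which 2 were called in the main test. Endothelial (0.312) and adipocyte (0.182) were lost there, and oviduct was called higher (0.00651).

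Direction turned for 17 results, 16 of them when one wild-type adult ovary was left out. For adult mutant against wild-type ovary the medians ran, over the left-out arrays, from -1.80 to 0.0233 for the cholesterol synthesis list and from -0.34 to 1.25 for the oocyte list. The gene values ran from -1.32 to 1.24 for Fshr, -2.10 to 0.92 for Amh, -2.93 to 2.11 for Bhmt, -0.97 to 1.40 for Pla2g4c, -0.68 to 1.44 for Gdf9, -0.86 to 1.26 for Zp1, -0.68 to 0.69 for Mos, -1.90 to 1.53 for Star, -1.11 to 0.70 for Hmgcs1, -1.62 to 0.78 for Dhcr7 and -0.67 to 0.41 for Fdft1, none of which passed with all arrays. For testis against wild-type ovary they ran from -1.06 to 3.98 for Bhmt, -0.60 to 1.38 for Sqle and -1.32 to 1.29 for Idi1. At P3 the steroidogenic list turned from higher to lower with fry (adjusted p = 0.0499), at a median of 0.19 and a mean of -0.28. Where one array is left out of a pair, the lone array is assumed to vary like the other groups.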

Other observations

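The tests in this part were chosen after the data were seen.

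Families of genes that share a symbol stem were tested for more calls than expected between adult mutant and wild-type ovaries, over 302 families with at least 8 measured genes and both directions (604 one-sided Fisher's exact tests). These tests treat the genes of a family as independent, so their p values do not measure variation between animals. Genes of the large ribosomal subunit were lower in 16 of 36 cases where 2.4 were expected (adjusted p = 1.68e-07), with small changes such as those of Rpl10a (-0.75 ± 0.11) and Rpl28 (-0.64 ± 0.09). Cct genes, of the chaperonin that folds actin and tubulin, were lower in 5 of 9 cases, among them Cct7 (-0.70 ± 0.10), against 0.599 expected (adjusted p = 0.0278). Kinesin genes were lower in 10 of 38 cases (2.53 expected, adjusted p = 0.0278), led by the mitotic motors Kif11 (-1.71 ± 0.12) and Kif15 (-1.68 ± 0.19), while the neuronal-type motors Kif21a (2.15 ± 0.21) and Kif1a (1.88 ± 0.18) rose. Solute carriers were higher in 55 of 352 cases (33.6 expected, adjusted p = 0.0278), among them the riboflavin transporter Slc52a3 (4.29 ± 0.18) and Slc2a3, a glucose transporter (1.32 ± 0.10). These example genes were chosen after their values were seen. The ribosomal and chaperonin counts held under quantile normalization and median centring (13 and 16, and 5 and 5). Without wild-type ovary 1 the ribosomal count was 10 (adjusted p = 0.0393). With the ovaries alone in the fit the ribosomal count was 6 (adjusted p = 0.0803) and the kinesin count 6 (adjusted p = 0.0868), and without wild-type ovary 1 the kinesin count was 7 (adjusted p = 0.545) and the solute carrier count 56 (adjusted p = 0.126). Without mutant ovary 1 the kinesin and solute carrier counts were 7 and 48 (adjusted p = 0.096 and 0.0826), and without mutant ovary 3 they were 7 and 48 (adjusted p = 0.165 and 0.0525).

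The 2 wild-type adult ovaries resembled each other less (r = 0.976 across genes) than the mutant ovaries did (0.989 to 0.991) or the testes (0.995 to 0.996). Wild-type ovary 1 was higher in follicle genes, with Amh at 9.05 against 6.03, Fshr at 8.31 against 5.75 and 19 of 20 oocyte genes. Wild-type ovary 2 was higher in genes of several lists, with Star at 11.2 against 7.73, Hsd17b7 at 11.6 against 7.71, all 5 corpus luteum genes (median difference -2.03) and all 12 cholesterol synthesis genes (median difference -1.85). Markers of other cells moved with them: 6 of 7 adipocyte genes (median difference -1.22) and all 7 endothelial genes (-0.62) were higher in wild-type ovary 2, with Car3 at 9.27 against 5.65. Plin4, which is on none of the lists and was picked for its large difference, stood at 9.79 against 5.64. A different stage of the ovarian cycle, fat tissue left on the organ or both may be behind this contrast between 2 animals, and none was tested. Cycle stage was not recorded in the labels used here, and without wild-type ovary 2 the cholesterol list's median between mutant and wild-type ovaries moved to 0.02.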
